A study of Mus musculus with 4 samples.

How the data were processed

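Nuclear RNA was measured in mouse 46c embryonic stem cells (ESC) and in neural progenitor cells (NPC) obtained from them with the N2B27 protocol, 2 samples per group. 46c is an ESC line with a fluorescent reporter of neural commitment. Per the labels' protocols, chromatin was prepared from nuclei without RNase, RNA was extracted with TRIzol, amplified with a whole transcriptome kit and labelled with Cy3 by random priming. The product carries no strand, so RNA from either strand of a region gave the same signal. The labels name no DNase step. Each sample was hybridised to 1 custom Agilent tiling array read in 1 colour. Groups and replicate numbers came from the sample titles. All 4 arrays lay on 1 slide with 1 scan, so no slide or scan batch could be tested.

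The deposited scanner files give spot intensity. Per the file headers, Agilent Feature Extraction 11.5.1.1 subtracted the background and replaced low intensity values by a floor of each array, with no normalization between arrays. The same files give yes or no marks (unit other) for spots well above background, saturated spots and outlier spots, set by that program, per the file headers. The series table holds the authors' own values on a log2 scale, as judged from the values, and the submitters' processing notes name limma without its version. Their normalization, centring and filter are not given in the sources used here. The column medians were 4.95 and 4.95 for ESC 1 and ESC 2, and 4.97 and 4.99 for NPC 1 and NPC 2. Of 48316 probes, 6777 had no value in that table. The columns of ESC 2, NPC 1 and NPC 2 followed the ranks of their own scanner intensity minus local background (Spearman 1 over probes). The column of ESC 1 did not (0.873 with its own scanner file, 0.900 with that of ESC 2). The authors' values served only as an alternative.

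The probes are 60 bases long and placed on mm9, per the file headers. The 48316 probes fell into 39 tiles, a tile being a run of probes with no gap above 50 kb. The other 3188 spots were controls and were left out, as were outlier spots on the array concerned. The tile with the most probes on chromosome 5 is called the Shh tile here. This is an inference from the stated aim of the series and from the chromosome of Shh in the gene table, not a match of coordinates. The gene table is on GRCm38. It served only for the names and order of the neighbours of Shh, and its coordinates were neither printed nor matched to probes. Genes, exons, the Shh start and the planned intervals upstream of it therefore could not be placed, and no gene is named from a position. The planned tests of genes, fixed gene lists and Shh intervals were not run for that reason. Without probe sequences, GC content and repeated matches were not examined.

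Values were log2 intensity minus each array's 75th percentile. The rule fixed before the data were examined took that percentile over all probes, or over the probes well above background on all arrays if under 50% of the probes were well above background. The share was 42.5% and 44.6% in ESC 1 and ESC 2, 54.1% and 54.3% in NPC 1 and NPC 2, and 48.9% over all arrays. The rule did not say which share counts. It was read as the share over all arrays, which gives the 15356 probes well above background on all 4 arrays, and the other reading is given beside the array-wide counts of windows, stretches and probes. Probe values were averaged per array in windows of 5 kb with at least 5 probes, which left 964 windows. Differences are NPC minus ESC on the log2 scale, tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the single term). P-values were adjusted by Benjamini-Hochberg over all windows, over all probes, or over all stretches, and a call means an adjusted p under 0.05. No exact test of 2 against 2 arrays can go below p = 0.333. The number of arrays limits the precision. Nothing in the labels says that the arrays of a group come from separate cultures, so p-values measure only the spread between these samples, which may be technical. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

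Several choices were made after the data had been seen. A stretch is a run of at least 3 adjacent windows in which at least 50% of the probes were well above background in the mean of either group, which gave 41 stretches. Stretches took the place of the gene test, after fits of whole tiles had also been tried. In all, 9 scalings were run on the scanner files: the main one, 2 fixed beforehand (each array's median over the probes above background, and normexp with an offset of 50 followed by quantile normalization) and 6 added later. The added ones were the percentile over all probes, a common floor, the percentile without the chromosome 12 tile, the median of control spots named SRN, each array's median over its windows, and, last, the median over the SRN spots of each spot's deviation from its own mean over the arrays. The counts of calls shared by all 9 scalings were also chosen later. The rules for reading the tests of the scaling in the Shh tile and of undifferentiated cells in NPC 2 were made stricter after their values had been seen, which left both explanations open. For normexp the median spot and background intensities were used, since the mean spot column is not used here. Its offset of 50 lies above each array's median probe signal, which ran from 8.87 to 17.6 after background subtraction. Normexp changes are therefore compressed and not on the same scale as the main ones.

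The named windows follow a rule fixed beforehand: among called windows whose groups do not overlap, the 10 with the largest rise and the 10 with the largest fall. Other alternatives fixed beforehand were windows of 2 and 10 kb, at least 10 probes, the median over probes, dim probes left out, a trend and robust prior, a replicate block, the authors' values, and each array left out. The steps were tested on simulated data made from the real probe means, with 200 of the 964 windows changed. The window test recovered 95.5% of windows changed by 2 on the log2 scale, 67.2% of those changed by 1 and 9.09% of those changed by 0.5, and 5.74% of its calls were false. The single-probe test, run on 48316 simulated probes, recovered 9.86% of probes changed by 2, 0.83% at 1 and 0.0931% at 0.5, and 5.60% of its calls were false. The simulation gave all probes the same noise SD and both groups the same spread of a window, and had no signal floor and no offset between arrays. In the real data the spread could differ between groups, as in the chromosome 12 stretches, where NPC varied more. The simulated rates therefore leave out errors from the floor, the scaling and unequal spreads, and those for single probes may not hold for the real probes.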

Results

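Nuclear RNA of ESC and NPC was read on a tiling array that covers a region of chromosome 5 taken to hold Shh, which encodes a signalling protein that patterns the neural tube and limbs, and further regions on other chromosomes and elsewhere on chromosome 5. Shh has Rbm33 and Rnf32 as its nearest protein-coding neighbours in the gene table, followed by Cnpy1 and En2 on one side and Lmbr1 and Nom1 on the other. Lmbr1 is known to hold a limb enhancer of Shh in an intron. Signal was well above background for 43.6% ± 1.49 of the probes in ESC and 54.2% ± 0.0995 in NPC (SD, n = 2 each). This rise was not general: the share went from 25.0% to 71.5% in the chromosome 12 tile and from 45.2% to 41.3% in the Shh tile. Negative control spots passed the same limit at 1.93% on average. Arrays of one group resembled each other more than arrays of different groups, with Spearman coefficients across probes of 0.879 for the ESC pair and 0.830 for the NPC pair, against at most 0.669 between groups. Probes are not independent replicates.

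The first comparison asked where nuclear RNA over the Shh tile differs between ESC and NPC, the stated aim of the series. The longest stretch of signal in the tile, at chromosome 5: 29520001-29710000 (mm9), fell in NPC. Its level was -2.16 ± 0.18 in ESC and -3.23 ± 0.31 in NPC (log2 relative to the scaling percentile, SD, n = 2), a change of -1.08 (SE 0.19) and a 2.11-fold higher level in ESC. A shorter stretch at 28515001-28535000 changed by -1.34 (SE 0.30). With normexp, whose offset compresses log2 changes, these 2 changes were -0.50 and -0.62, and both were still called. No window of the tile was called higher in NPC. The annotation that would say which genes these stretches cross is not used here.

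Of the 261 windows in the Shh tile, 129 were called lower and 0 higher in NPC (limma, Benjamini-Hochberg), and at an unadjusted p under 0.05 the counts were 181 and 0. The median change of the tile was -0.53, against -0.34 for all 964 windows and -0.43 for the windows outside the chromosome 12 tile. Medians of the other tiles lay on both sides of that of the Shh tile. The number of lower calls rested on the scaling: it was 119 with each array's median, 155 with normexp, 256 with the percentile over all probes, 237 with the median over windows, 46 with a common floor, 20 with the percentile taken without the chromosome 12 tile, 22 with the median change per SRN control spot (1 higher), and 6 with the array medians of those spots, where 2 windows were called higher and the median change of the tile was 0.073. The windows called lower under all 9 scalings numbered 6 and start at 29510001, 29610001, 29625001, 29630001, 29650001 and 29665001. Among them were changes of -2.12 (SE 0.41, 7 probes) at 29630001 and -1.94 (SE 0.17, 42 probes) at 29610001. With normexp these were -0.74 and -1.11, and with the median over probes -3.69 and -1.98. The window at 29630001 dropped out with at least 10 probes or with dim probes left out. Without ESC 1 no window of the tile was called, and without ESC 2 none was called either, with 71 and 36 lower at an unadjusted p under 0.05; without NPC 1 the count was 194.

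**Figure D1:**
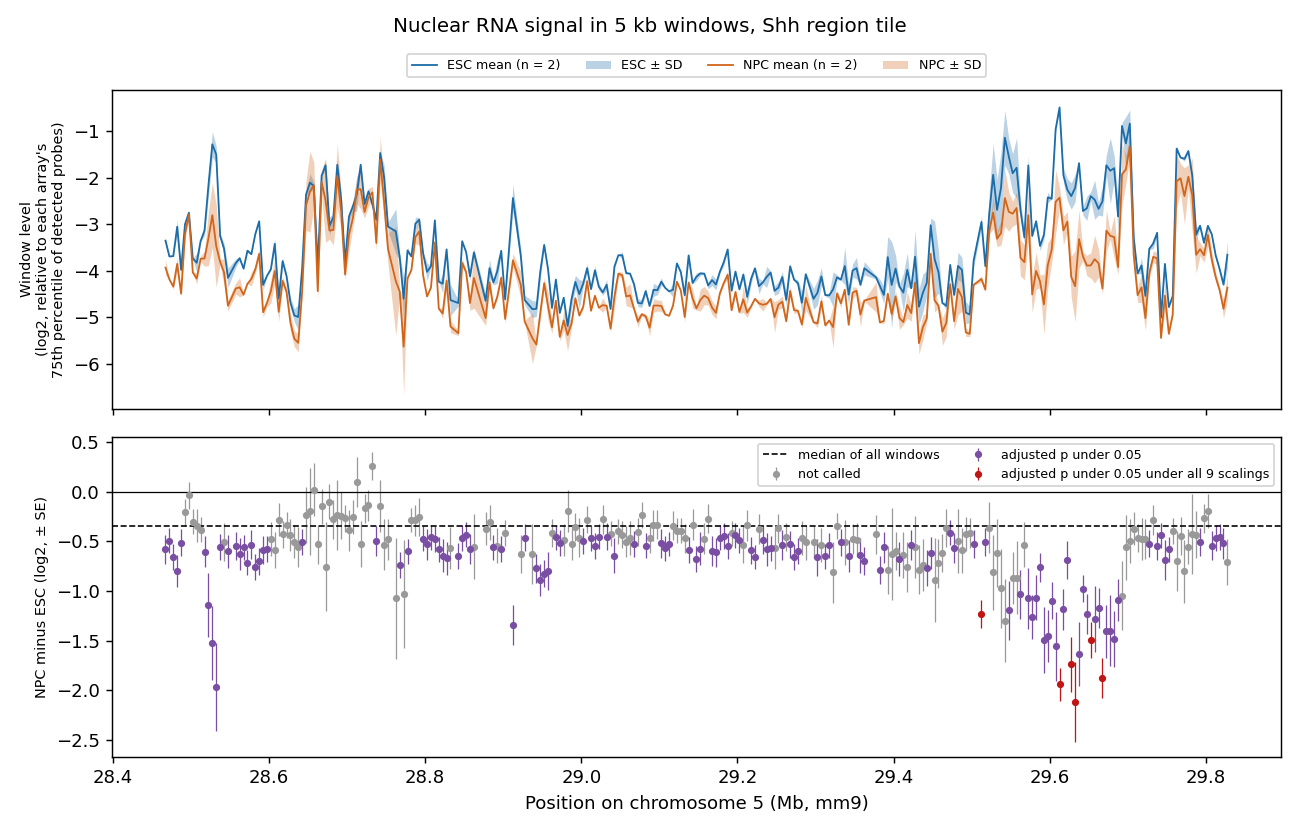
Nuclear RNA level (upper panel, log2 relative to each array's 75th percentile of detected probes, group mean with SD as shading, n = 2) and NPC minus ESC (lower panel, log2 with SE) in 5 kb windows along the Shh tile of chromosome 5 in mm9. The 6 red windows were called lower under all 9 scalings, and the dashed line marks the median of all windows at -0.34.

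The Shh tile held 6 stretches with signal above background. The longest, 29520001-29710000, had an adjusted p of 0.00844 in the limma fit over 41 stretches, and relative to the median of all windows its change was -0.74. It contained 26 lower windows of 38. Its adjusted p was 0.0516 when the percentile left out the chromosome 12 tile and 0.0750 when the array medians of the SRN spots set the scale, with changes of -0.86 and -0.47. The stretch at 28515001-28535000 had an adjusted p of 0.0137, 0.0703 when the percentile left out the chromosome 12 tile, and 0.0344 with those SRN medians (change -0.74). Of 17 alternatives, the longest stretch kept its call in 15 and this one in 16. The stretch at 29760001-29810000 changed by -0.48 (SE 0.16, limma adjusted p = 0.0468) and kept its call in 7 of 17 alternatives. It was at -0.29 without NPC 2 and -0.66 without NPC 1, at -0.27 with normexp and at -0.86 with the percentile over all probes. Its adjusted p was 0.0565 with each array's median, 0.0529 with the trend prior, 0.0847 with dim probes left out, 0.0671 with the median over probes, 0.0640 with a common floor, 0.282 without the chromosome 12 tile, 0.385 with the median change per SRN spot, and 0.261 and 0.284 without ESC 1 and ESC 2. It turned to 0.13 with the SRN medians (adjusted p = 0.593). The 3 stretches between 28645001 and 28755000 had values of -0.14, -0.23 and -0.25 and did not pass (limma adjusted p = 0.725, 0.371 and 0.160). The first was at 0.33 without NPC 2 and at -0.60 without NPC 1, called each way (adjusted p = 0.00935 and 9.65e-06). The other 2 were called lower without NPC 1 (-0.53 and -0.37), with the percentile over all probes (-0.61 and -0.63) and with the median over windows (-0.43 and -0.44), and the last also with the authors' values (adjusted p = 0.0263). All 3 were above 0 with either SRN scaling. Within each array, the longest stretch minus the mean over probes of the other 5 was 0.02 and 0.29 in ESC and -0.50 and -0.47 in NPC, a difference of -0.64 (SE 0.13).

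Single probes of the Shh tile gave 240 lower and 22 higher calls among 12390 probes. Over the whole array 759 of 47900 tested probes were called lower, 20 of them in the chromosome 12 tile of 9836 probes. Lower calls were thus about as frequent in the Shh tile as in the other tiles outside chromosome 12. Higher calls, 5138 over the array with 4151 on chromosome 12, were rarer in the Shh tile. The share of its probes well above background was 45.2% ± 2.37 in ESC and 41.3% ± 1.18 in NPC (SD, n = 2).

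The second comparison covered the other tiles, which the labels do not describe. The tile at chromosome 12: 54345487-55182412 (mm9, 9836 probes) rose along nearly its whole length in NPC. Probes well above background made up 25.0% ± 0.71 in ESC and 71.5% ± 5.38 in NPC (SD, n = 2). The median change of its windows was 2.03. Its size is not well measured, since most ESC probes there were not well above background, and it ranged from 0.54 with normexp to 2.64 with the array medians of the SRN spots. Its stretches rose by 2.32 (SE 0.30) at 54345001-54595000, by 2.18 (SE 0.26) at 54605001-55030000 and by 1.15 (SE 0.17) at 55035001-55185000. With normexp the 3 rises were 0.70, 0.65 and 0.26, with the array medians of the SRN spots 2.92, 2.79 and 1.76, and with the median over probes 3.73, 3.64 and 1.98. With the authors' values the last was 0.74.

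In the chromosome 12 tile, 163 of 168 windows were called higher, 1 lower and 4 were not called (limma, Benjamini-Hochberg). The lower window was the last one, 55180001-55185000, at -0.91 (SE 0.13), and it was not called under all 9 scalings. Over the 9 scalings, 158 to 167 windows were called higher, and 156 were called in all of them. The adjusted p of the 3 stretches was 0.00432, 0.00405 and 0.00558. The 10 windows with the largest rise of the whole array all lay in this tile, from 3.17 at 54405001 to 3.48 at 54800001, or 1.08 to 1.28 with normexp. In ESC only 19.5% to 39.0% of their probes were well above background, so neither these sizes nor their order is well measured. Without ESC 1 or without ESC 2 no window passed, with 151 and 145 higher at an unadjusted p under 0.05, while the 3 stretches still passed. Those stretch fits leaned on the spread pooled over all stretches. NPC 2 lay below NPC 1 across the tile, with array means of -2.91 and -2.18, against -4.53 and -4.60 in ESC 1 and ESC 2.

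**Figure D2:**
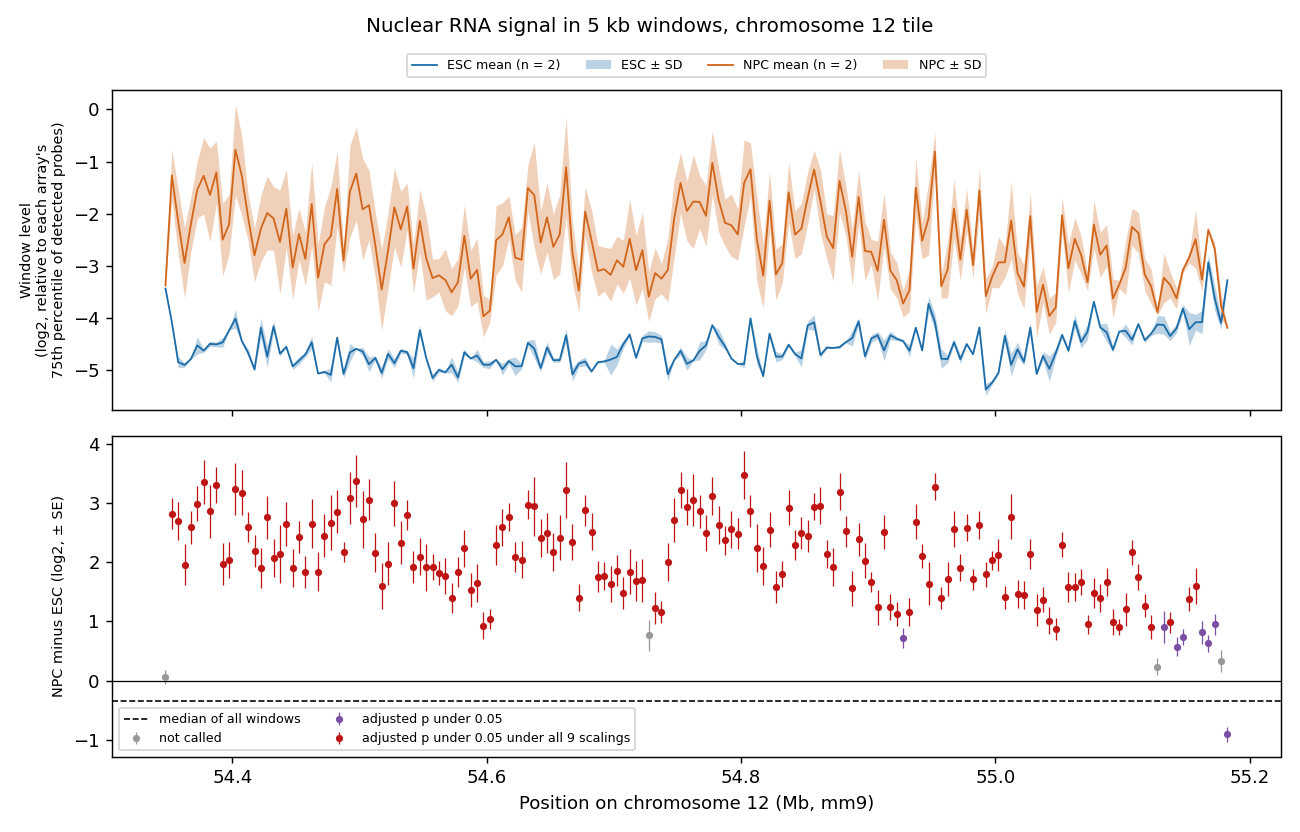
Nuclear RNA level (upper panel, log2 relative to each array's 75th percentile of detected probes, group mean with SD as shading, n = 2) and NPC minus ESC (lower panel, log2 with SE) in 5 kb windows along the chromosome 12 tile in mm9. The 156 red windows were called higher under all 9 scalings, and the last window lies below 0 at -0.91.

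Outside these 2 tiles the changes went both ways. The stretch at chromosome 3: 34460001-34585000 rose by 1.33 (SE 0.19), and 16 of its 25 windows were called higher under all 9 scalings. Signal fell over chromosome 14: 46995001-47010000, at -1.56 (SE 0.14), over chromosome X: 7530001-7555000, at -1.48 (SE 0.13), and over chromosome 6: 122645001-122715000, at -1.17 (SE 0.15). With normexp these 4 changes were 0.36, -0.71, -0.55 and -0.52, and with the array medians of the SRN spots the 3 falls were -0.95, -0.87 and -0.57. These 4 stretches and the 3 of chromosome 12 were the ones called under all 9 scalings. The largest falls of single windows were -2.90 (SE 0.19) at chromosome 7: 152050001-152055000 and -2.89 (SE 0.13) at chromosome 4: 55540001-55545000.

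Of the 41 stretches, 10 were called higher, 17 lower and 14 neither way (limma, Benjamini-Hochberg). The balance turned with the scaling: higher and lower stretches were 4 and 24 with the percentile over all probes, 4 and 21 with normexp, 8 and 23 with the median over windows, 11 and 5 without the chromosome 12 tile, 13 and 8 with the median change per SRN spot, and 17 and 4 with the array medians of the SRN spots. They were 10 and 16 with each array's median and 10 and 15 with a common floor. The adjusted p was 0.00485 on chromosome 3, 0.00181 on chromosomes 14 and X, and 0.00432 on chromosome 6. The Shh tile windows at 29630001 and 29610001 given above are also among the 10 with the largest falls, and the other 6 were those at chromosome 6 from 122700001, 122705001 and 122710001 (from -2.11 to -1.92), chromosome 17 from 35645001 (-1.99), chromosome 5 from 28530001 (-1.97) and chromosome 7 from 152045001 (-1.89). With normexp the 10 falls ran from -1.59 to -0.74. Of these 6 windows, the one at 28530001 was not called under all 9 scalings. Without ESC 1 there were 4 higher and 6 lower stretches, and without ESC 2 there were 4 and 5.

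**Figure D3:**
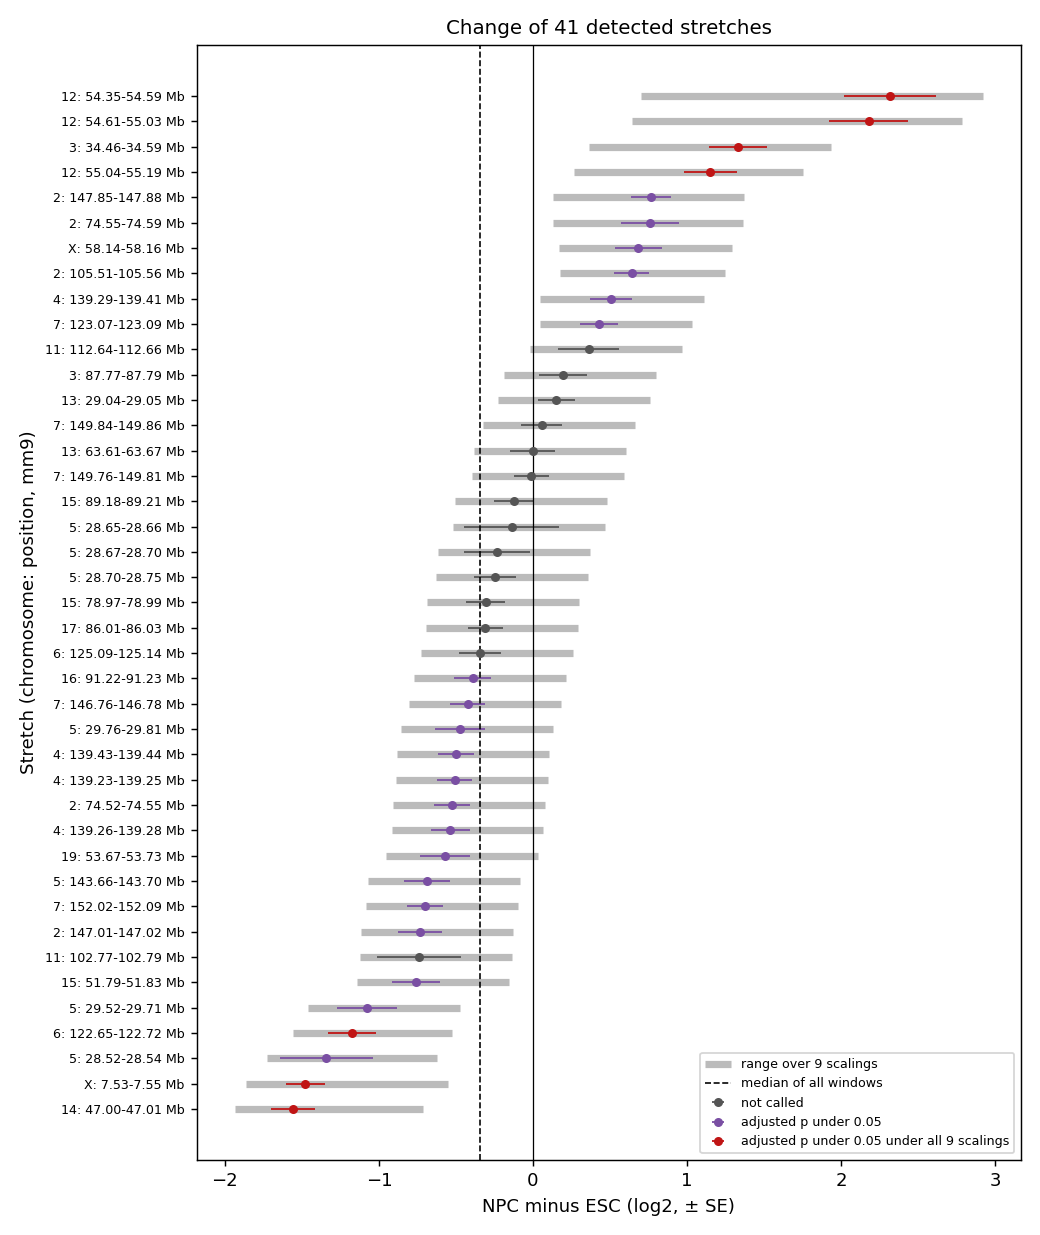
Change of the 41 stretches (NPC minus ESC, log2, points with SE) with the range over 9 scalings as grey bars, by chromosome and position in mm9. The 7 red stretches were called under all 9 scalings, and the dashed line marks the median of all windows at -0.34.

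Over the whole array, 212 of 964 windows were called higher in NPC, 282 lower and 470 neither way, and 163 of the 212 lay on chromosome 12. At an unadjusted p under 0.05 there were 229 higher and 381 lower. Higher and lower calls split as 211 and 260 with each array's median, 188 and 353 with normexp, 195 and 622 with the percentile over all probes, 203 and 539 with the median over windows, 218 and 128 with a common floor, 226 and 65 with the percentile taken without the chromosome 12 tile, 246 and 72 with the median change per SRN spot, and 303 and 28 with the array medians of the SRN spots. The higher share of the calls ranged from 23.9% to 91.5%. All 9 scalings shared 185 higher and 28 lower windows. The median change of all windows shifted from -0.34 to between -0.72 and 0.26 over the scalings. Without ESC 1, and without ESC 2, 0 windows passed (smallest adjusted p in limma 0.111 and 0.113), with 186 and 182 higher and 131 and 113 lower at an unadjusted p under 0.05; without NPC 1 the lower calls were 432. Single probes gave 5138 higher and 759 lower calls of 47900 tested, 4151 of the higher ones on chromosome 12. The counts were 4153 and 1135 with the percentile over all probes, and the lower ones were 3478 without NPC 1 and 1454 without NPC 2.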

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

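The control spots named SRN drew attention because they carry signal outside the comparisons. On average 56.4% ± 1.23 of them were well above background (SD over the 4 arrays), against 1.93% of the negative control spots. What these spots hold is not stated in the sources used here. Relative to the scaling percentile, the median NPC minus ESC of those above background on all arrays was -0.29, while their array medians differed by -0.60. Scaling to those medians therefore shifts the windows by more than the typical spot changed, and the counts under it rest on the medians. Scaling by the median change per spot was also run: it shifts the windows by 0.29 and gave 246 higher and 72 lower windows, against 303 and 28.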

How the results depend on the processing

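The 6 added scalings and the whole-tile fit were chosen after seeing the data. Scalings that shift a whole array moved windows by at most 0.60 (log2), less than any change of the 20 named windows. The direction of these windows could therefore not turn there. Of the 20 named windows, all kept their direction in every alternative run, and outside the fits with an array left out 277 values kept their call and 1 lost it. Without either ESC array, all 20 lost it. The 7 stretches shared by all scalings kept direction and call in all 17 alternatives. These include the scalings by which the 7 were chosen, and that choice fixed the outcome there. Among the others, the authors' values, the trend prior and the median over probes could have failed. The dim filter kept probes above background on both arrays of either group, which enlarged these changes, as from 2.32 to 3.10 on chromosome 12 from 54345001. With the replicate block or an array left out, the stretch fits leaned on the spread pooled over all stretches. In limma the adjusted p of that stretch was 0.00432, and 1.74e-12 with the block. A call kept there says little about the spread between samples. The cause of the changes below was not tested, except where stated. Windows lower numbered 442 (210 in the Shh tile) with the authors' values, 148 (65) with the median over probes, 622 (256) with the percentile over all probes, 128 (46) with a common floor, 65 (20) without the chromosome 12 tile, 28 (6, with 2 higher) with the array medians of the SRN spots ("SRN spots" below), 72 (22, with 1 higher) with the median change per SRN spot, and 539 (237) with the median over windows. Other window sizes changed the number tested: higher windows were 481 at 2 kb (371 on chromosome 12) and 115 at 10 kb (83). Higher stretches were 4 with normexp, 5 with the authors' values, 4 with the percentile over all probes, 17 with SRN spots (4 lower) and 4 with whole tiles. Lower stretches were 5 without the chromosome 12 tile and 8 with the median change per SRN spot. Probes were 2928 higher with normexp and 469 lower with SRN spots.

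Signs turned in Shh tile stretches: 28645001 was 0.079 without the chromosome 12 tile, 0.47 with SRN spots and 0.33 without NPC 2 (-0.60 without NPC 1); 28665001 was 0.37 with SRN spots and 0.061 without NPC 2 (-0.53 without NPC 1); 28700001 was 0.36 and 29760001 was 0.13 with SRN spots. With the median change per SRN spot the first 3 were 0.15, 0.054 and 0.041. Signs also turned outside the Shh tile. Over all tiles, 132 called windows changed sign with SRN spots and 1 with normexp. Stretches called lower that turned positive with SRN spots included chromosome 16 from 91220001 (0.21), chromosome 19 from 53670001 (0.034) and chromosome 7 from 146760001 (0.18). Those on chromosomes 4 and 2 are given below, and the remaining lower stretches stayed below 0. Leaving out 1 array at a time, where the lone array is assumed to vary like the other group, gave 0 to 237 windows higher (0 to 165 on chromosome 12), 0 to 432 lower (0 to 194 in the Shh tile), 738 to 3478 probes lower, 4 to 12 stretches higher and 5 to 24 lower. Without an ESC array the spread rests on the NPC pair, with 3.06 degrees of freedom.

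With the replicate block, 144 windows (55 in the Shh tile) and 409 probes were lower. Same-numbered arrays deviated together with a correlation of 0.0473 over windows, from only 2 pairs, so the numbers are not taken as pairing. Gene, gene-list, Shh-interval, exon, intron, GC-content (with and without block) and repeated-match alternatives were not run, for want of coordinates on the same build and of probe sequences. Signal over background limits the Shh tile, where fewer than 50% of probes were above it in either group.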

Other observations

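Several tiles held changes in opposite directions side by side. At chromosome 4: 139230459-139455219 the stretch 139290001-139415000 was higher in NPC (0.51, SE 0.14), between stretches that were lower at 139230001-139255000 (-0.51, SE 0.11), 139260001-139275000 (-0.54, SE 0.13) and 139425001-139440000 (-0.50, SE 0.12). At chromosome 2 the stretch 74515001-74545000 was lower (-0.53, SE 0.12) and its neighbour 74550001-74595000 higher (0.76, SE 0.19). The 4 lower values turn positive with the array medians of the SRN spots, at 0.099, 0.069, 0.10 and 0.079, while the 2 higher ones shrink to as little as 0.048 and 0.13 over the 9 scalings and are not called under all of them. In the tile at chromosome 7: 152006254-152088283, the window 152050001-152055000 was at -2.90 (SE 0.19) and the window 152085001-152090000 at 1.79 (SE 0.14), each called under all 9 scalings. At chromosome 3 the tile had 17 higher and 4 lower windows of 51, and all 17 lay in the stretch from 34460001. Of these, 16 of the higher and 0 of the lower windows were called under all 9 scalings. The ESC 1 column of the authors' table had a Spearman coefficient of 0.873 with its own scanner file and 0.900 with that of ESC 2.

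The tests below were chosen after the results had been seen, except the normexp and array-median scalings behind the count of 158, which were planned. The first pattern is the broad lowering in the Shh tile. A signal floor that lies lower in the scaled NPC arrays (by -0.39) may account for part of it: with a common floor, 14.1% of the 92 dim lower windows stayed called, and their median change went from -0.56 (SD 0.15) to -0.39 (SD 0.15) with a similar standard error, so the calls ended because the change shrank, not because it vanished. Of the 82 bright windows of the tile, those that are not dim, 37 were called lower, and 33 were called lower with a common floor. Their median change was -0.65, against -0.52 for the 179 dim windows of the tile. For the bright windows these values argue against the floor as the source of the lower calls. The choice of scaling cannot be told apart from a change of the tile. Of the 129 lower windows 6 remained with the array medians of the SRN spots. That scaling adds 0.60 to every window, which fixes the loss. The percentile taken without the chromosome 12 tile adds 0.21 and gave 20 lower windows. The median change per SRN spot adds 0.29 and gave 22. The percentile over all probes and the median over windows shift the other way and gave 256 and 237. Both references, like the main one, include the chromosome 12 tile, which rose in NPC. An offset shared by dim windows elsewhere cannot be told apart from a change of the tile. Dim Shh windows lay -0.16 below dim windows of the other tiles, with the chromosome 12 tile left out. The 95% bootstrap interval over windows was -0.21 to -0.12, from 2000 draws, which leaves out the error between arrays. The fall of the longest stretch is not explained by an offset of the whole tile. Within arrays its change lay -0.64 (SE 0.13) below the mean over probes of the other 5 stretches. It did not lie below each of them, since the stretch at 28515001-28535000 changed by -1.34. A lower nuclear RNA level in NPC remains a hypothesis for the longest stretch.

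The second pattern is the rise on chromosome 12. Genomic DNA carried over into the NPC preparations would raise every tile. Scaling removes a rise shared by all tiles, so the median change of the other tiles, -0.43, cannot exclude such carry-over. An equal rise of all tiles on the log2 scale would not set chromosome 12 apart, where the median change was 2.03 in the same arrays. With the array medians of the SRN spots the other tiles were at 0.18 and chromosome 12 at 2.64. With the median change per spot they were at -0.14 and 2.32. Scaling does not account for it, since at least 158 of 168 windows were called under each scaling. A difference between the cell types is a hypothesis from these data, and a copy number gain of the region in the NPC samples was not tested.

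The third pattern is that NPC 2 lay below NPC 1 on chromosome 12, by a median of -0.72. More undifferentiated cells in NPC 2 cannot be told apart from other causes. They would lift the windows that are lower in NPC, and in NPC 2 the 28 windows lower under all scalings had a median difference of -0.26. That is 1 array against 1 array, and the scaled floor of NPC 2 also lay lower, by -0.29. A lower sensitivity of the NPC 2 array cannot be told apart either. The 182 bright windows called neither way lay at -0.11 (SE 0.04) in NPC 2, and the scaling to bright probes largely fixes that outcome. A difference in how far the samples had differentiated may remain, untested.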
